A study of Mus musculus with 5 samples.

How the data were processed

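Polyadenylated RNA from RPE and choroid of C57BL/6J mice was measured in 5 libraries, 2 from filtered air and 3 from cigarette smoke. Per the labels' protocols, mice entered at 2 months of age and were either exposed in a chamber to smoke for 6 months, with daily sessions of 2.5 hours on 5 days of each week, or lived in filtered air. Per the labels, stranded poly(A) libraries were made from 100 ng of RNA and sequenced as paired ends of 126 bases. How many mice entered each library is not given in the sources used here, so p-values measure the spread between these samples.

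The submitters' processing notes name Trimmomatic 0.36, kallisto 0.45.0, edgeR 3.26.6 and the mouse build GRCm38.p6. The order and settings of these steps are not given in the sources used here. The deposited gene table and transcript table hold estimated counts, with 52962 genes and 141196 transcripts, and neither is scaled to a common depth. Gene and transcript totals were equal in each library, yet of 16439 genes with at least 10 counts on average 65.7% differed by under 10% from the sum of their transcripts in all libraries, so the gene counts are not plain sums. The method of summing is not given in the sources used here. A further deposited table, treated as a score, holds CPM (counts scaled to a common library total) divided by TMM (trimmed mean of M values) factors over all genes, which was found by recomputing it from the gene counts. Estimated counts split reads among transcripts of a gene and among near-identical genes, which adds an error that the tables do not carry.

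Gene symbols, biotypes and coordinates were those deposited with the normalised CPM. Transcript names, types, lengths and coordinates, and the link from transcript to gene, came from GENCODE mouse release 21. That release matched 52002 genes and 138258 transcripts by identifier. On alternative patch sequences lay 779 genes, of which 207 were tested. In the fixed lists 2 symbols were renamed to those of the deposited annotation.

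Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr by group, TMM factors, estimateDisp and the quasi-likelihood test, with no covariate and no block, and Benjamini-Hochberg adjusted p under 0.05. After the filter 17133 genes and 45080 transcripts were tested. The gene fit had 3 residual degrees of freedom, a prior of 3.41, and a biological coefficient of variation of 19.6%. TMM factors ran from 0.971 to 1.04 and totals from 13614666 to 16160331 estimated counts. Levels are TMM-normalised CPM with the SD over libraries, and log2 fold changes are given as smoke over air with their SE.

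Gene lists were tested with limma 3.58.1. camera compares a list with all other genes, here with a preset inter-gene correlation of 0.01 and, beside it, with a correlation estimated for each list; fry tests whether the genes of a list move on balance one way and does not compare the list with other genes. p-values were adjusted over all 51 lists, 29 of them themes and 22 markers of cell types, which had been fixed before the data were examined. With the preset correlation 17 lists passed camera, 3 as higher and 14 as lower, against 0 with an estimated correlation (smallest adjusted p = 0.307). fry called 1 list, and its test for changes in either direction called 5. The text describes 27 lists, which hold all 17 calls: circadian clock, interferon response, antigen presentation, complement, chemokines and adhesion, AhR xenobiotic response, Nrf2 antioxidant response, pattern recognition and NF-kB, epithelial-mesenchymal transition, Wnt signalling, RPE differentiation and transcription factors, visual cycle, cholesterol synthesis, mitochondrially encoded, ribosomal proteins, and the markers of neutrophils, erythrocytes, macrophages and microglia, rods, cones, bipolar cells, retinal pigment epithelium, melanocytes, Schwann cells and myelin, skeletal muscle, fibroblasts and sclera, and surface epithelium. None of the other 24 passed camera, with adjusted p from 0.0805 to 0.870, and in 4 of them the median, mean and test differed in sign.

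Isoform usage was tested with edgeR's diffSpliceDGE in genes with at least 2 tested transcripts, with Simes p-values per gene. Because this test made excess calls on simulated data, a ratio test was added: limma on the log2 ratio of each transcript to the rest of its gene, with 1 CPM added to both, and a spread for each transcript.

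The rule for named genes was fixed before the data were examined. It takes the 10 largest rises and falls past the threshold and, where fewer than 5 pass in a direction, the 5 with the smallest p in that direction, among genes of at least 1 log2 CPM with all smoke libraries beyond both air libraries and a symbol that is not a clone or predicted name. From each described list it takes up to 3 risen and 3 fallen members past the threshold or, where none passes, the 2 most abundant members. For transcripts it takes the 5 with the smallest p in each direction, and for isoform usage the 5 genes with the smallest p. Other list members named in the text were chosen after their values were seen, most of them as those with the smallest p in their list. Some genes that the rule or the lists would name are not reported here, and they stay in the tests and in the counts of their lists.

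The tests were tried on simulated data with the means, spreads and library sizes of these libraries. Among 17133 simulated genes edgeR recovered 7.46% of 1.5-fold, 37.3% of 2-fold and 80.3% of 4-fold changes, with 9 false among 92 calls. DESeq2 recovered 23.9%, 61.2% and 92.4%, with 38 false among 156 calls, and limma-voom made 5 false among 81. Among 45080 simulated transcripts edgeR made 7 calls, 1 of them false, and recovered 9.09% of 4-fold changes, while 208 of 262 DESeq2 calls were false. For isoform usage in 9753 simulated genes diffSpliceDGE made 36 calls, 28 of them false, and recovered 8 of 166 altered genes, and the ratio test made 0 calls. For lists with 10 of 50 moved by 0.6 on the log2 scale, camera with the preset correlation called all 10 and no unmoved list. With an estimated correlation camera called 9, and fry called 9 and 1 unmoved list. Correlation between genes was not among the properties taken from these libraries. The simulated lists therefore cannot show how often camera with the preset correlation makes false calls in lists of correlated genes.

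Alternatives were other scaling factors (RLE, upper quartile), filters (none, at least 1 CPM in 2 libraries, at least 10 counts in 2 libraries for isoforms), tools (DESeq2 1.42.0, limma-voom, the legacy form of edgeR's test, limma-trend on the log2 of the deposited normalised CPM plus 1 or 0.1), the replicate number as a block, the mean rod marker level as a covariate, and leaving out each of the 5 libraries. The ratio test and the mean erythrocyte marker level as a covariate were added after the data were examined. Other scaling moved the median log2 fold change of all genes, −0.01 with TMM, by less than 0.1. Replicates of a group were compared before averaging, and every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 18.1 to 66.8). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with 0.1 CPM added before taking logs.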

Results

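Polyadenylated RNA from the retinal pigment epithelium (RPE) and choroid, the pigmented support layer of the photoreceptors and the vascular bed under it, was sequenced from C57BL/6J mice kept in filtered air or exposed to cigarette smoke for 6 months. There were 2 air libraries and 3 smoke libraries, each a separate biological replicate per the labels, from mice aged 8 months. Estimated counts summed to 15343956 and 15991097 in the air libraries and to 15866912, 16160331 and 13614666 in the smoke libraries. A further air replicate had been dropped by the submitters for neural retina tissue and was not analysed here. The comparison asked which genes, and in particular which innate immune and RPE differentiation genes, differed after chronic smoke exposure.

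At the level of single genes 5 of the 6 smallest p-values belonged to regulators of the circadian clock, and the other to the neutrophil granule gene Ngp (edgeR adjusted p = 0.0957), which averaged 0.46 log2 CPM. Ciart, a repressor of the clock activator complex (ENSMUSG00000038550, chromosome 3, 95878503 to 95882251), averaged 25.4 ± 2.19 CPM (TMM-normalised counts, mean ± SD, n = 2) in air and 3.37 ± 0.758 CPM (n = 3) in smoke. Arntl, which encodes the activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), averaged 11.5 ± 0.826 CPM in air and 29.3 ± 1.51 CPM in smoke. The clock output factor Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203) averaged 192 ± 51.3 CPM in air and 58.5 ± 1.53 CPM in smoke. The period gene Per1 (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960) averaged 108 ± 24.6 CPM in air and 39.4 ± 0.447 CPM in smoke. Coordinates are on GRCm38.p6, and all 4 are protein-coding genes.

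None of these genes passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment over the 17133 genes tested. The log2 fold change of smoke over air was −2.90 ± 0.21 (SE) for Ciart, with an adjusted p of 0.0945. It was 1.35 ± 0.13 for Arntl, −1.72 ± 0.16 for Dbp and −1.46 ± 0.15 for Per1, each with an adjusted p of 0.0957 in edgeR. The clock repressor Nr1d2 was at −0.91 ± 0.09 (adjusted p = 0.0957, edgeR) and Ggt1, a gamma-glutamyltransferase of glutathione metabolism, at −1.41 ± 0.15 (adjusted p = 0.110). On the positive side stood Prb1 at 1.06 ± 0.11 (adjusted p = 0.0957), the angiopoietin-like Angptl7 at 1.39 ± 0.15 (adjusted p = 0.110), Crispld2 at 0.87 ± 0.11 and the ADAM family member Adam11 at 1.03 ± 0.13. These 10 genes were picked among those with every smoke library beyond both air libraries. Without air replicate 2 edgeR's adjusted p was 0.0187 for Dbp and Per1, 0.0274 for Ciart, 0.0431 for Arntl, 0.0468 for Ggt1 and 0.0481 for Nr1d2, and without air replicate 1 it was 0.0390 for Dbp, 0.0799 for Ciart, 0.0989 for Per1, 0.289 for Arntl and Nr1d2 and 0.310 for Ggt1.

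edgeR called 0 genes at an adjusted p under 0.05, with 2715 genes at an unadjusted p under 0.05, where 857 would be expected by chance. Of these, 1193 were higher and 1522 lower in smoke. DESeq2 called 256 genes higher and 284 lower, while the legacy form of edgeR's test and limma-voom called 0. All smoke libraries lay above both air libraries in 2792 genes (16.3%) and below both in 3142 (18.3%), where chance gives 10% each. Without air replicate 1 edgeR called 0 genes higher and 6 lower, and without air replicate 2 it called 14 higher and 121 lower, with the lone air library then assumed to vary like the smoke libraries.

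The circadian clock list changed in both directions, and its balance lay below that of other genes. Of its 19 tested members 6 had positive and 13 negative log2 fold changes, with a median of −0.57. Npas2, a partner of BMAL1, was at 1.63 ± 0.31 beside Arntl, and the period and nuclear receptor repressors Per2 and Nr1d1 were at −0.91 ± 0.13 and −1.68 ± 0.26. The output factors Hlf and Tef were at −0.67 ± 0.11 and −0.63 ± 0.10, and the repressor Bhlhe40, 1 of the 2 most abundant members, was at −0.41 ± 0.14. The list passed camera with a preset correlation (adjusted p = 1.1e-09), against an adjusted p = 0.307 with an estimated correlation, and it was the 1 list of 51 that passed fry (adjusted p = 0.00516). No member passed over all genes tested, while adjusted over the list alone 4 passed as higher and 12 as lower. DESeq2 called 4 members higher and 9 lower. In edgeR Nr1d1 passed over all genes without air replicate 1 (adjusted p = 0.0390) or 2 (0.0431). The adjusted p from fry was 0.0759 without smoke replicate 1, 0.0734 without smoke replicate 2 and 0.404 with the rod marker level as a covariate, within a range of 0.00248 to 0.404 over the alternatives tried.

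**Figure D1:**
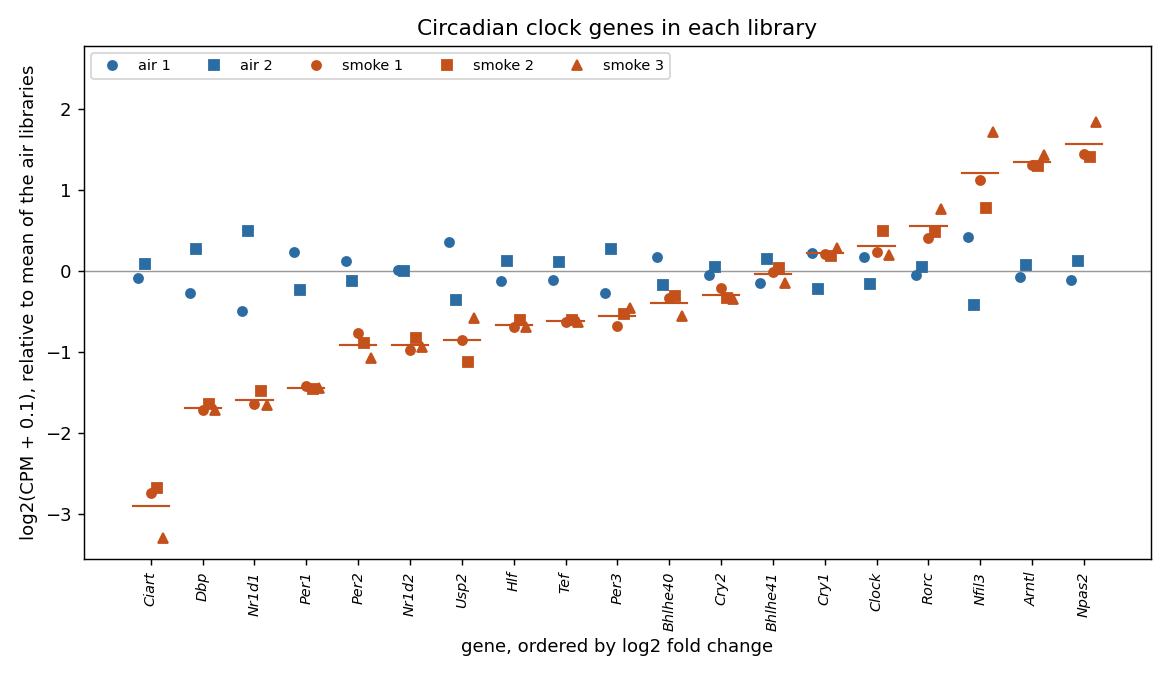
Log2 CPM (with 0.1 CPM added) of the 19 clock genes in each library, relative to the mean of the air libraries, ordered by log2 fold change. Points are single libraries and bars are means of the 3 smoke libraries; Ciart, Dbp, Nr1d1 and Per1 lie lowest and Nfil3, Arntl and Npas2 highest in smoke.

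Interferon-responsive genes fell as a group in smoke. Of 35 tested members 33 had negative log2 fold changes, and the median of the list was −0.61 (camera adjusted p = 1.19e-12). The adjusted p = 0.63 with an estimated correlation, and the list did not pass fry. Ifit3, an RNA-binding effector of the antiviral state, averaged 167 ± 5.59 CPM in air and 87.0 ± 10.7 CPM in smoke, a log2 fold change of −0.94 ± 0.12. Its relative Ifit1 was at −1.18 ± 0.16, the ubiquitin-like modifier Isg15 at −1.04 ± 0.22 and the oligoadenylate synthetase Oas1a at −1.30 ± 0.25. The most abundant members, Ifitm3 and Ifi27, were both at −0.67, with SEs of 0.13 and 0.09. No member passed edgeR over all genes, 15 passed as lower adjusted over the list alone, and DESeq2 called 8 lower. Mean log2 CPM of the list was 4.09 and 4.50 in the air libraries and 3.88, 3.65 and 3.80 in the smoke libraries. Without air replicate 2 the median was −0.34, with 28 of 35 members negative (camera adjusted p = 0.00150), and without air replicate 1 it was −0.60.

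**Figure D2:**
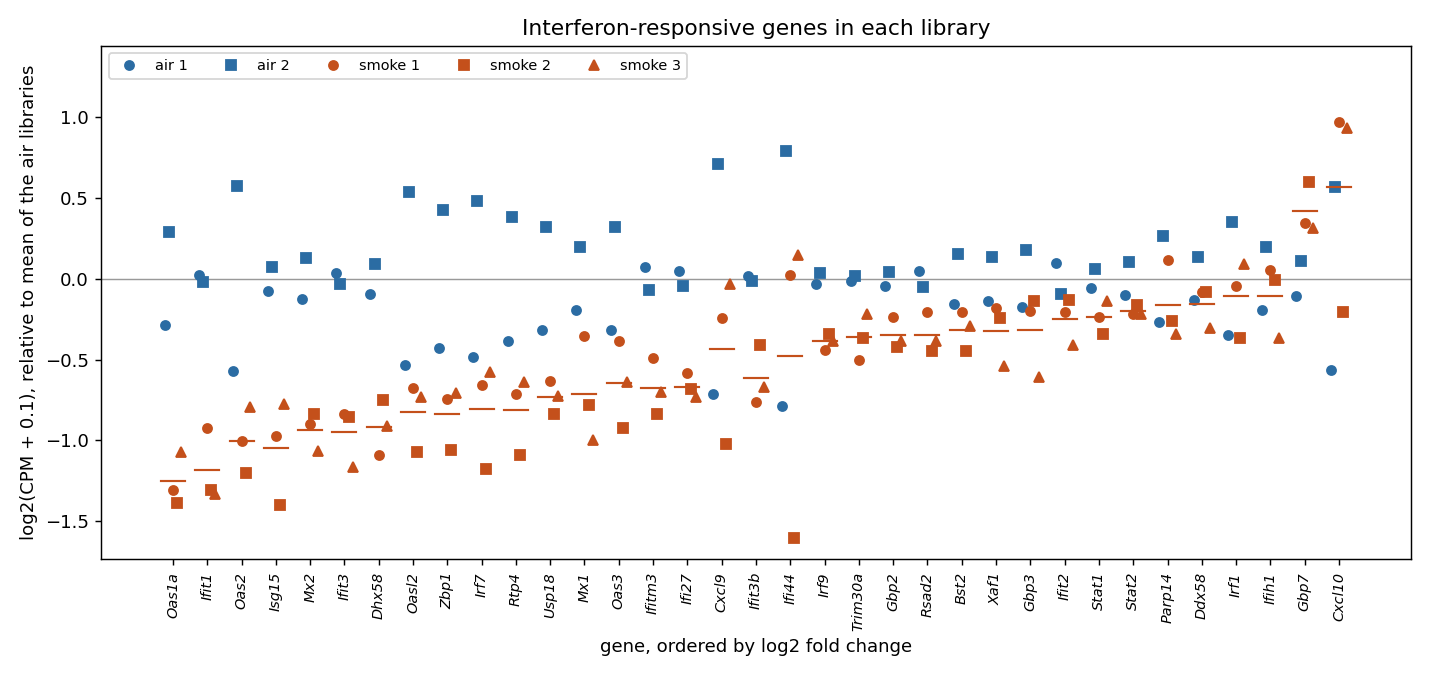
Log2 CPM (with 0.1 CPM added) of the 35 interferon-responsive genes in each library, relative to the mean of the air libraries, ordered by log2 fold change. Points are single libraries and bars are means of the 3 smoke libraries; 33 of the 35 genes have a negative fitted log2 fold change, and air replicate 2 lies above air replicate 1 for most genes.

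Antigen presentation and chemokine genes fell too, with smaller medians. In the antigen presentation list 13 of 18 members were negative and the median was −0.34 (camera adjusted p = 0.000207; adjusted p = 0.691 with an estimated correlation). The class II genes H2-Eb1 and Cd74 were at −0.96 ± 0.19 and −0.90 ± 0.18 and the class I heavy chain H2-K1 at −0.61 ± 0.14, while the abundant class I genes B2m and H2-D1 were at −0.08 ± 0.12 and 0.17 ± 0.14. Adjusted over the list alone 7 members passed as lower, none did over all genes, and DESeq2 called 6 lower. In the chemokine and adhesion list 17 of 22 members were negative and the median was −0.46 (camera adjusted p = 0.00166; adjusted p = 0.63 with an estimated correlation), with 0 members called by edgeR over all genes, over the list alone or by DESeq2, and 1 higher and 8 lower at an unadjusted p under 0.05. Ccl8 was at −1.21 ± 0.34 and the adhesion molecule Icam1 at −0.52 ± 0.15, against 0.53 ± 0.22 for the abundant Cxcl12. The antigen presentation call was lost without air replicate 2 (camera adjusted p = 0.278) and with the rod marker covariate (adjusted p = 0.106).

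Complement genes and pattern recognition genes did not pass camera with all libraries and no covariate. Like every list but that of the clock, they did not pass fry's test of a balance one way either. The complement list had 8 positive and 14 negative members (camera adjusted p = 0.0971), with the abundant Clu at −0.21 ± 0.20. Adjusted over the list alone 3 members passed as lower: C1qtnf5 at −0.92 ± 0.12, the classical pathway component C4b at −0.62 ± 0.12 and the recognition subunit C1qb at −0.57 ± 0.11. DESeq2 called the same number, 3, as lower. The complement list passed camera with the rod (adjusted p = 0.0428) or erythrocyte (0.0182) marker covariate. The pattern recognition and NF-kB list reached a camera adjusted p of 0.191. Macrophage and microglia markers had a median of −0.09 (camera adjusted p = 0.0545), and 2 members passed as lower adjusted over the list alone, among them the fractalkine receptor Cx3cr1 at −0.94 ± 0.23. The macrophage list passed camera as lower without air replicate 1 (adjusted p = 0.00928) or smoke replicate 1 (0.0161), with no filter (0.0359) and with the rod (0.00160) or erythrocyte (0.0276) marker covariate.

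Neutrophil and erythrocyte markers fell and varied between the air libraries. All 7 tested neutrophil genes were negative, with a median log2 fold change of −3.44 (camera adjusted p = 8.85e-10; adjusted p = 0.63 with an estimated correlation). The calprotectin subunits S100a8 and S100a9 were at −3.47 ± 0.51 and −3.44 ± 0.67, the granule protein gene Ngp averaged 3.10 ± 1.38 CPM in air and 0.0199 ± 0.0345 CPM in smoke, and the receptor gene Csf3r was at −0.05 ± 0.16. All 7 tested erythrocyte genes were negative, with a median of −2.27 (camera adjusted p = 3.91e-07; adjusted p = 0.63 with an estimated correlation). The globin genes Hbb-bs and Hba-a2 were at −2.50 ± 0.47 and −2.33 ± 0.48 and the heme synthesis gene Alas2 at −2.43 ± 0.58. No member of either list passed over all genes, 5 of each passed as lower adjusted over the list alone, and DESeq2 called 2 neutrophil and 3 erythrocyte genes lower. Mean log2 CPM of the neutrophil list was 2.65 and 1.42 in air against −0.0975, −0.397 and −0.313 in smoke, and that of the erythrocyte list was 7.55 and 5.61 in air against 5.05, 5.43 and 4.64 in smoke. Globin genes have near-identical copies, so the split of counts among them is uncertain. Sizes depended on which air library was kept. Without air replicate 2 the log2 fold changes were −4.00 for S100a8, −4.15 for S100a9 and −7.11 for Ngp. They were −3.13 for Hbb-bs, −2.97 for Hba-a2 and −3.13 for Alas2 in that fit. Without air replicate 1 they were −2.64 for S100a8, −1.99 for S100a9 and −6.18 for Ngp. That fit gave −1.37 for Hbb-bs, −1.15 for Hba-a2 and −1.03 for Alas2.

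Genes that respond to smoke constituents through the aryl hydrocarbon receptor (AhR) did not move as a group, although the receptor's target Cyp1a1 had a large fold change. Cyp1a1, a monooxygenase of polycyclic aromatic hydrocarbons, averaged 0.357 ± 0.316 CPM in air and 4.28 ± 1.62 CPM in smoke, a log2 fold change of 3.53 ± 0.64. It did not pass over all genes (edgeR adjusted p = 0.170), was the 1 member that passed adjusted over the list alone (adjusted p = 0.0130), and was the 1 member DESeq2 called. Of the 11 tested members 5 were positive and 6 negative: Ugt1a7c was at 0.72 ± 0.31, Cyp1b1 at −0.47 ± 0.35, the receptor repressor Ahrr at −0.28 ± 0.36, and the abundant members Aldh3a1 and Nqo1 at −0.09 ± 0.28 and −0.05 ± 0.10. The list's median of −0.05 differed in sign from its mean of 0.30 and from the direction camera gave (higher, adjusted p = 0.345). The Nrf2 antioxidant list had 14 positive and 15 negative members (camera adjusted p = 0.765). Its abundant ferritin genes Fth1 and Ftl1 were at −0.05 ± 0.17 and 0.16 ± 0.16, the stress enzyme Hmox1 at −0.24 ± 0.19, the glutathione reductase Gsr at 0.63 ± 0.14 and the cystine transporter Slc7a11 at −2.26 ± 0.69. No Nrf2 list member passed edgeR over all genes or over the list alone, 3 higher and 3 lower were at an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower. The value of Slc7a11 was −3.02 without air replicate 2 (edgeR adjusted p = 0.0429) and −0.53 without air replicate 1 (adjusted p = 0.746).

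RPE identity genes did not pass camera as groups with all libraries and no covariate, and most of them had positive log2 fold changes. Retinal pigment epithelium markers had 12 positive and 4 negative members (camera adjusted p = 0.224), and the visual cycle list, whose enzymes and carriers regenerate the photoreceptor chromophore, had 9 positive and 3 negative (adjusted p = 0.245). The retinoid isomerase gene Rpe65 averaged 2155 ± 171 CPM in air and 2815 ± 297 CPM in smoke, a log2 fold change of 0.39 ± 0.18. Lrat, which supplies its substrate, was at 0.13 ± 0.15, and the abundant Rgr and Ttr at 0.16 ± 0.29 and −0.13 ± 0.28. RPE differentiation and transcription factor genes had a median of 0.18, a mean of −0.01 and a camera direction toward higher values (adjusted p = 0.126), so the mean differed in sign. Adjusted over that list alone 3 members passed as higher: the pigment cell transcription factor Mitf at 0.84 ± 0.14, the cadherin Cdh3 at 0.91 ± 0.14 and Crim1 at 0.76 ± 0.17. DESeq2 called 3 members higher, and the abundant Ctsd and Enpp2 were at −0.10 ± 0.20 and −0.26 ± 0.21. The differentiation list passed camera toward higher values without smoke replicate 3 (adjusted p = 0.00974), with the replicate block (0.00809) and with the erythrocyte marker covariate (0.0248). With the rod marker covariate its direction and that of the retinal pigment epithelium markers turned (camera adjusted p = 0.938 and 0.929).

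Genes of the epithelial-mesenchymal transition list fell on balance. Of 27 tested members 20 were negative and the median was −0.31 (camera adjusted p = 0.00918; adjusted p = 0.691 with an estimated correlation). Adjusted over the list alone 4 members passed as lower, among them genes of matrix-associated proteins and of a calcium-binding protein: the matricellular protein gene Ccn2 was at −1.48 ± 0.25, periostin (Postn) at −1.01 ± 0.21 and the calcium-binding S100a4 at −0.98 ± 0.24. The abundant Thbs1 was at −0.0011 ± 0.15. No member passed over all genes, and DESeq2 called 1 higher and 4 lower. The Wnt signalling list reached a camera adjusted p of 0.262, and its receptor gene Lrp5 was at 0.49 ± 0.10, the 1 member DESeq2 called. The call of the transition list was lost without air replicate 1 (camera adjusted p = 0.109), without smoke replicate 3 (0.150), with the replicate block (0.0686) and with the erythrocyte marker covariate (0.867). The Wnt list passed without air replicate 2 (camera adjusted p = 0.0480) and with the rod marker covariate (0.00385).

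Mitochondrially encoded, ribosomal protein and cholesterol synthesis genes fell by small amounts as lists. All 13 mitochondrially encoded genes were negative, with a median of −0.48 (camera adjusted p = 8.52e-10; adjusted p = 0.63 with an estimated correlation). Their share of all counts was 9.32% and 9.68% in the air libraries and 7.43%, 6.23% and 7.59% in the smoke libraries. The abundant mt-Co1 and mt-Cytb were at −0.44 ± 0.45 and −0.47 ± 0.31, and mt-Atp8 at −0.73 ± 0.11. Adjusted over the list alone 2 of the 13 passed as lower, and DESeq2 called 7. Of 40 ribosomal protein genes 38 were negative, with a median of −0.25 (camera adjusted p = 8.52e-10; adjusted p = 0.63 with an estimated correlation). Rpl4 and Rplp0 were both at −0.15, with SEs of 0.11 and 0.10. Adjusted over the list alone 18 ribosomal genes passed as lower and DESeq2 called 10, though many processed pseudogenes share their sequence. Cholesterol synthesis genes had 17 of 20 negative members and a median of −0.37 (camera adjusted p = 0.000698; adjusted p = 0.691 with an estimated correlation), with Sqle at −0.78 ± 0.27, Srebf2 at −0.11 ± 0.15 and Fdft1 at −0.07 ± 0.15. In the cholesterol list edgeR called 0 over all genes or over the list alone and DESeq2 0, with 7 at an unadjusted p under 0.05. The cholesterol call was lost without air replicate 1 (camera adjusted p = 0.246) and with the rod (0.0944) or erythrocyte (0.846) marker covariate.

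Rod, cone and bipolar cell markers of the neural retina were present in all libraries and fell in smoke. All 20 rod photoreceptor genes were negative, with a median of −0.44 (camera adjusted p = 8.85e-10; adjusted p = 0.675 with an estimated correlation). Gnat1 was at −0.47 ± 0.18, the arrestin gene Sag at −0.84 ± 0.19, Pdc at −0.66 ± 0.12 and the channel subunit Cnga1 at −0.86 ± 0.16. Adjusted over the list alone 7 rod genes passed as lower and DESeq2 called 4. Mean log2 CPM of the rod list was 7.33 and 7.21 in air and 6.59, 6.65 and 7.11 in smoke. Cone photoreceptor genes (median −0.62, camera adjusted p = 4.71e-05, against adjusted p = 0.63 with an estimated correlation) and bipolar cell genes (median −0.57, camera adjusted p = 0.00662, against adjusted p = 0.691 with an estimated correlation) went the same way, with 12 of 13 and 10 of 12 negative members. No cone or bipolar gene passed over all genes; adjusted over the list alone 1 cone gene and 0 bipolar genes passed as lower, DESeq2 called the same numbers, and 5 and 3 were lower at an unadjusted p under 0.05. The bipolar call was lost without air replicate 2 (camera adjusted p = 0.133). With the rod marker covariate the rod (0.969), cone (0.515) and bipolar (0.978) calls were lost, and the bipolar direction turned.

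Markers of neural crest derivatives rose as lists. Melanocyte genes had 8 of 10 positive members and a median of 0.44 (camera adjusted p = 0.00166; adjusted p = 0.63 with an estimated correlation), and Schwann cell and myelin genes had 7 of 10 and a median of 0.61 (camera adjusted p = 0.00166; adjusted p = 0.63 with an estimated correlation). The lists share Sox10, a neural crest transcription factor at 0.67 ± 0.12, and the cadherin Cdh19 at 0.87 ± 0.17. Ednrb was at 0.80 ± 0.19, while the pigment enzymes Tyrp1 and Dct were at 0.64 ± 0.22 and −0.52 ± 0.32 and the myelin genes Mal and Pmp22 at −0.43 ± 0.30 and −0.03 ± 0.11. Adjusted over each list alone 3 members passed as higher, none passed over all genes, and DESeq2 called 3 of each. All 16 skeletal muscle genes were positive (median 0.61, camera adjusted p = 0.00166, against adjusted p = 0.691 with an estimated correlation), but 0 passed edgeR over all genes or the list alone, 0 passed DESeq2 and 0 had an unadjusted p under 0.05. Mean log2 CPM of the muscle list was 8.83 and 9.72 in air and 9.88, 9.39 and 10.2 in smoke. Of surface epithelium genes most were negative (median −0.60, 9 of 11 negative, camera adjusted p = 0.00819, against adjusted p = 0.691 with an estimated correlation), with 0 members called by edgeR over all genes, over the list alone or by DESeq2 and 2 lower at an unadjusted p under 0.05. Mean log2 CPM of that list was 5.05 and 5.51 in air and 3.52, 5.12 and 4.46 in smoke. Fibroblast and sclera genes did not pass (camera adjusted p = 0.0545), although Dcn was at 1.09 ± 0.24, Lum at 0.79 ± 0.17 and Pdgfra at 0.97 ± 0.19. Calls were lost for melanocyte genes without air replicate 2 (camera adjusted p = 0.0622) and with the rod marker covariate (0.595), for Schwann cell genes with the rod (0.214) and erythrocyte (0.105) marker covariates, for surface epithelium without air replicate 2 (0.593) and with the rod marker covariate (0.309), and for muscle without air replicate 1 (0.463) or smoke replicate 3 (0.0629). The fibroblast list passed camera as higher without smoke replicate 3 (adjusted p = 0.000951), with no filter (0.0184), with the replicate block (0.00110) and with the erythrocyte marker covariate (0.0341), and its direction turned with the rod marker covariate (0.284). Muscle was called lower with the erythrocyte marker covariate (camera adjusted p = 0.0341).

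**Figure D3:**
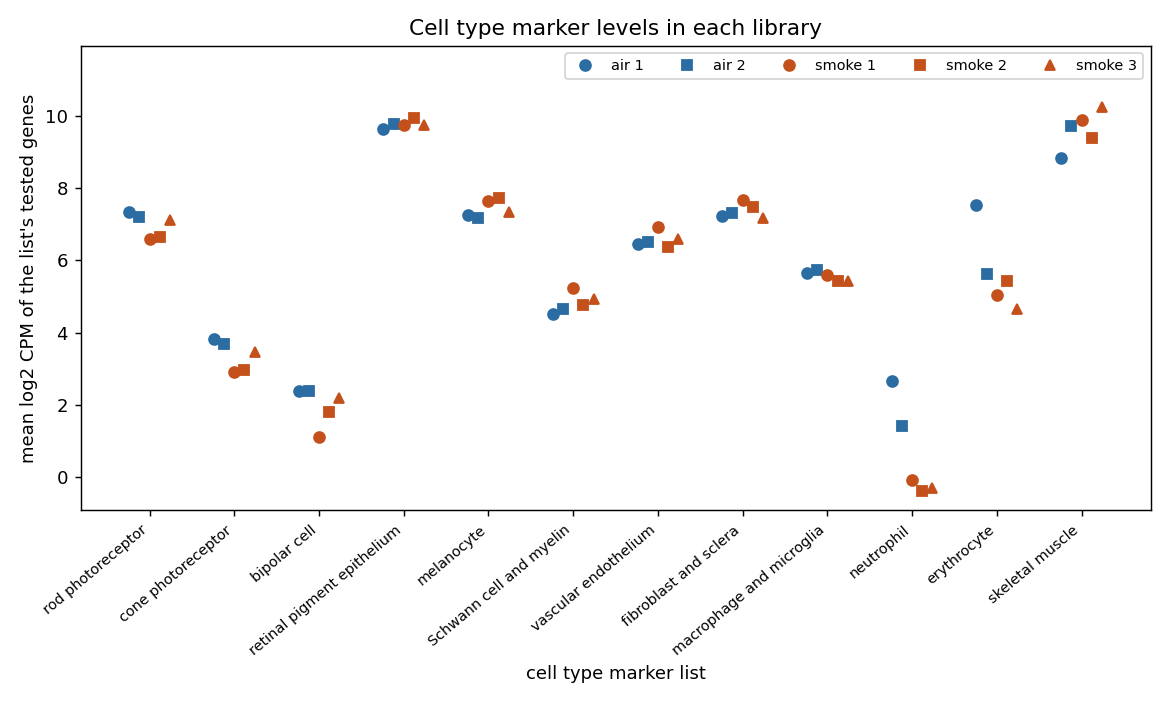
Mean log2 CPM over the tested genes of 12 cell type marker lists in each of the 5 libraries, with 1 point per library. Neutrophil and erythrocyte markers differ between the air libraries as well as between the groups, rod markers run from 6.59 to 7.33, and retinal pigment epithelium markers lie above rod markers in every library.

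At the transcript level 3 of 45080 transcripts passed edgeR, each an isoform that was near absent in 1 group. Casc4-202 rose from 0.133 ± 0.00359 CPM in air to 10.6 ± 1.88 CPM in smoke (adjusted p = 0.0423). Hsd17b12-204, a non-coding transcript of a fatty acid elongation enzyme gene, fell from 28.3 ± 6.22 CPM to 0.0414 ± 0.0718 CPM (adjusted p = 0.0423), and Tnpo2-202, from a nuclear import receptor gene, fell from 18.4 ± 0.120 CPM to 0.245 ± 0.223 CPM (adjusted p = 0.0441). Transcripts next by p did not pass: Fryl-201, Tspan3-203, Psap-202 and Axin1-202 on the higher side had adjusted p-values of 0.0647 to 0.0808 in edgeR, and Pitpnm2-205, Gm10275-203 and Myo18a-221 on the lower side 0.0535 to 0.0582. DESeq2 called 1062 transcripts higher and 764 lower, but on simulated transcript counts 208 of its 262 calls were false. That share depends on how many transcripts were altered in the simulation, so it need not hold for these calls. Leaving out any 1 library took the higher count from 1 to 0, and the lower count from 2 to 0 without air replicate 1, air replicate 2, smoke replicate 2 or smoke replicate 3.

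Isoform usage differed in 739 genes by the planned test, of which 166 had an unadjusted gene-level p under 0.05. In Rab7, a small GTPase of late endosomes (ENSMUSG00000079477, chromosome 6, 87999106 to 88045270), the protein-coding isoform Rab7-204 took 26.7% and 34.3% of the gene's estimated counts in the air libraries and at most 0.001% in smoke. Its estimated counts in the smoke libraries were 0.04, 0 and 0.01, and a count of 0 allows a share of up to 0.0180%. In Psap, the precursor of the lysosomal saposins (chromosome 10, 60277627 to 60302597), Psap-202 took 6.76% ± 0.083 (SD, n = 2) in air and 35.5% ± 4.98 (n = 3) in smoke. Otud5-202 of the deubiquitinase gene Otud5 took 29.8% ± 1.70 in air and 0.473% ± 0.819 in smoke, the retained-intron transcript Pcolce-209 took 9.55% ± 1.35 and 1.99% ± 0.479, and Mif4gd-204 took 18.2% ± 5.56 and 0, which allows up to 0.0749%. The limits cover counting error only. The gene-level log2 fold changes of these 5 genes were 0.15 for Rab7, −0.02 for Psap, 0.04 for Otud5, −0.25 for Pcolce and 0.51 for Mif4gd.

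The planned isoform test, edgeR's diffSpliceDGE, called 739 of 10365 genes, and a ratio test added after the data were examined called 21, all among the 739. Rab7 had an adjusted p of 1.75e-08 in the planned test and 0.0181 in the ratio test, and Mif4gd 8.3e-07 and 0.0451. Psap (ratio test adjusted p = 0.0780), Otud5 (0.0730) and Pcolce (0.134) passed the planned test alone. Visual cycle genes were among the 739, with 4 of 8 tested members (Rdh5, Rgr, Rlbp1 and Stra6), as were 5 of 10 retinal pigment epithelium markers (the same 4 and Trpm3) and 8 of 38 ribosomal protein genes. No gene of these lists passed the ratio test. Of all tested genes 7.13% were called, and enrichment of these lists was not tested. On simulated counts 28 of the planned test's 36 calls were false, while the ratio test made 0 calls there and recovered none of the 166 altered genes. The share of false calls depends on how many genes are altered, so the share among the 739 is not known. The planned test called 299 genes without air replicate 1, 440 without air replicate 2 and 481 without smoke replicate 2.

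**Figure D4:**
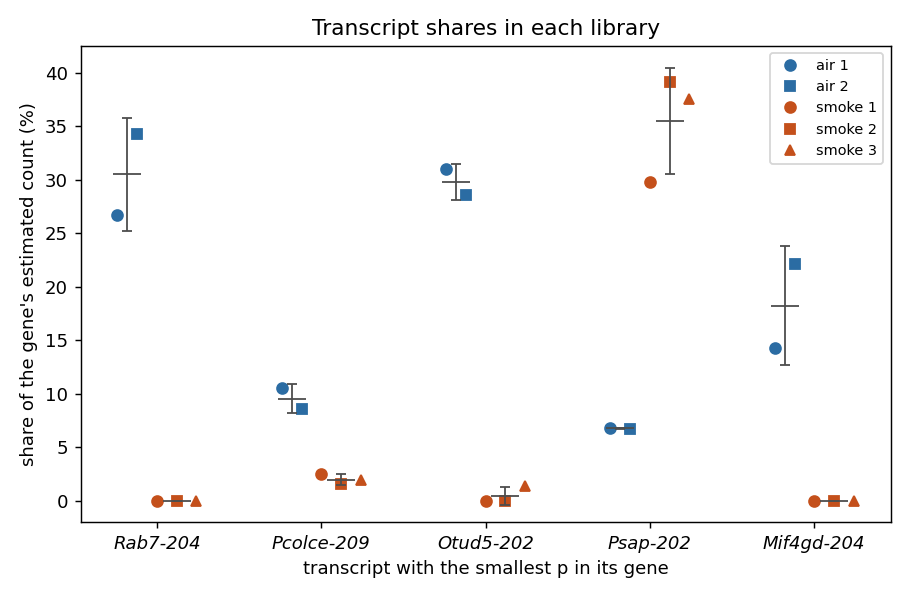
Share of the gene's estimated counts (%) held by the transcript with the smallest p in each of the 5 genes with the smallest p for isoform usage. Points are single libraries, and horizontal bars with whiskers are group means ± SD (n = 2 air, n = 3 smoke); the Psap transcript is higher and the other 4 are lower in smoke.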

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

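The tests with the ratio test and the erythrocyte marker covariate were chosen only after the results were seen; the other settings were fixed before the data were examined.

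edgeR called 0 genes under RLE and upper-quartile factors, either filter, the legacy test and the rod marker covariate, as did limma-voom and limma-trend on the deposited CPM. DESeq2 called 256 genes higher and 284 lower, the erythrocyte marker covariate 0 and 10, and leaving out 1 library 0 to 14 and 0 to 121. The 17 list calls became 28 with the erythrocyte marker covariate (14 shared), 14 with the rod marker covariate (9 shared), 0 with an estimated correlation and 1 with fry. Leaving out 1 library gave 18 to 21 list calls, of which 13 to 17 were shared. The adjusted p of the clock list in fry, 0.00516, became 0.404 with the rod and 0.155 with the erythrocyte marker covariate, and 0.0376 to 0.0759 with 1 library left out. Transcripts called higher and lower, 1 and 2, became 3 and 7 with no filter, 1062 and 764 with DESeq2, and 0 to 0 and 0 to 2 with 1 library left out. Isoform usage calls, 739, became 21 with the ratio test and 299 to 670 with 1 library left out. The rod difference of −0.49 log2 CPM became −0.48 with RLE factors and −0.42 with no factor. With 1 air library left the test assumes that it varies like the smoke libraries. The cause was not tested for any of these shifts.

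Replicate numbers match in 2 pairs and the labels do not say that they mark pairs, so nothing was taken as paired. Deviations from group means correlated at −0.0357 for replicates 1 and −0.266 for replicates 2. With 2 air libraries the air deviations mirror each other, so these correlations cannot settle whether the numbers mark pairs. With the replicate block edgeR called 0 genes, 0 transcripts higher and 0 lower, 221 genes for isoform usage and 23 lists by camera, 16 of them shared with the 17, and the call of the epithelial-mesenchymal transition list was lost (adjusted p = 0.0686). fry then called 0 lists, with an adjusted p of 0.179 for the clock list.

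Signs turned mostly for genes near 0, though Slc7a11, Dct and Cyp1b1 lay further from it with all libraries and no covariate. No tested gene passed edgeR over all genes with all libraries, so that threshold does not set the turned genes apart. Log2 fold changes of Thbs1 became 0.00704 with DESeq2, 0.00694 with RLE factors, 0.00212 with upper-quartile factors, 0.0151 with no filter, and 0.00087 and 0.000854 with limma-trend and 1 or 0.1 CPM added. With the replicate block the values that turned were Thbs1 at 0.0991, Csf3r at 0.0081 and Pmp22 at 0.0365. With the rod marker covariate the values that turned were Aldh3a1 at 0.25, Fdft1 at 0.20, Ahrr at 0.20 and Lrat at −0.13. With the erythrocyte marker covariate the values that turned were H2-D1 at −0.0697, Fth1 at 0.0281, Thbs1 at 0.16, Ctsd at 0.017, Srebf2 at 0.26, Fdft1 at 0.0829, Csf3r at 0.14, Dct at 0.36, Pmp22 at 0.0184, Cyp1b1 at 0.61, Hmox1 at 0.24 and Slc7a11 at 0.15. With 1 library left out the ranges were B2m −0.16 to 0.0169, Aldh3a1 −0.25 to 0.15, Thbs1 −0.11 to 0.11, Srebf2 −0.31 to 0.12, Fdft1 −0.18 to 0.0514, Csf3r −0.14 to 0.0459, Dct −0.93 to 0.0515, Mal −0.81 to 0.0886, Pmp22 −0.11 to 0.049, Cyp1b1 −0.94 to 0.25, Ahrr −0.45 to 0.0135, Hmox1 −0.50 to 0.0722. The cause was not tested.

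The camera direction turned for lists with these adjusted p-values. With the rod marker covariate they were 0.938 for RPE differentiation, 0.978 for bipolar cells, 0.284 for fibroblasts and sclera and 0.929 for retinal pigment epithelium. With the erythrocyte marker covariate they were 0.0829 for Nrf2, 0.846 for cholesterol synthesis, 0.0341 for skeletal muscle and 0.105 for Wnt signalling. With the replicate block the value was 0.753 for Nrf2. The direction also turned for Nrf2 without air replicate 1 (0.618) and without smoke replicate 3 (0.762) and for Wnt signalling without air replicate 1 (0.908). Over all 5 fits with 1 library left out, turned or not, the ranges were 0.164 to 0.839 for Nrf2 and 0.0480 to 0.927 for Wnt signalling. The cause was not tested.

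Depth was similar between libraries, and with 2 air libraries the simulated power at 2-fold was 37.3% for edgeR, which limits what a gene-level count of 0 can show.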

Other observations

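The tests of blood content, macrophages and neural retina, that of a single air library for interferon-responsive genes and the count over other splits were chosen only after the results were seen, and the retina and blood tests replaced earlier ones that rested on single libraries. The covariate fits that replaced them rest on few libraries too, as described below.

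Sex-linked transcripts did not go with the labels, which give equal numbers of females and males. The Y-linked genes were expressed in all 5 libraries, with Ddx3y at 50.6 to 75.8 CPM, Eif2s3y at 51.5 to 55.4, Kdm5d at 28.8 to 36.9 and Uty at 14.2 to 19.3. Xist, which is transcribed from the inactive X chromosome of females, was at 1.37 and 0.688 CPM in the air libraries and at 0.126, 0.124 and 0.0735 CPM in the smoke libraries. The long non-coding RNA Gm42418 took 1.10% of counts in air replicate 2 and between 0.0274% and 0.0505% in the other 4 libraries.

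Lysosomal and oxidative phosphorylation genes were among those called for isoform usage by edgeR's diffSpliceDGE, with 6 of 20 lysosome and autophagy genes (Ctsa, Ctsd, Map1lc3b, Npc2, Sqstm1 and Tfeb) and 6 of 28 nuclear oxidative phosphorylation genes. Of glycolysis genes 3 of 19 were called (Aldoa, Gapdh and Pkm), and no rod gene of 17 was. None of the called genes in these lists passed the ratio test, and on simulated counts 28 of 36 diffSpliceDGE calls were false. The ratio test recovered none of the 166 altered genes there, so failing it does not show that a call is false. Of all tested genes 7.13% were called, and enrichment of these lists was not tested.

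The clock genes differed between the groups as sets with opposite phase. The 6 genes that peak with Arntl had a median log2 fold change of 0.88, all positive, and the 11 that peak with Dbp and Per1 a median of −0.91, all negative, a difference of 1.79. A single air library does not account for it, since the difference was at least 1.72 without either air library. With the rod marker level as a covariate the difference was 2.07. Within the groups the rod level varied mostly through smoke replicate 3, and it also differed between the groups. The fit therefore cannot decide whether neural retina content is a cause. The covariate was the mean of the rod list itself, so that list's lost call (camera adjusted p = 0.969) was no separate check. In the same fit the clock list's adjusted p from fry went from 0.00516 to 0.404. A candidate explanation is a difference in clock phase at collection. Collection times are not given in the sources used here, so different collection times and a shift brought by the exposure both stay open.

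An even loss of macrophages would lower their markers as much as interferon-responsive genes, if both came from the same cells in the same proportion. The interferon median minus the macrophage median was −0.51 (permutation test over genes, p = 0.00207), which under that premise leaves a smaller part open. The premise was not tested, so a loss of only some macrophages stays open. The permutation treats genes of the same libraries as independent, so its p does not measure the spread between libraries. The macrophage list itself passed camera as lower with the rod or erythrocyte marker covariate. With the rod marker level as a covariate the interferon median was −0.69 (camera adjusted p = 5.66e-11, against adjusted p = 0.690 with an estimated correlation). That covariate again rests largely on smoke replicate 3, so the fit cannot decide whether neural retina content is a cause. With the erythrocyte marker level as a covariate the erythrocyte median went from −2.27 to −0.47. The interferon median stayed at −0.61 (camera adjusted p = 5.47e-25, against adjusted p = 0.579 with an estimated correlation). Within the groups the erythrocyte level varied mostly between the air libraries, and it also differed between the groups. This fit therefore cannot decide whether residual blood is a cause. The erythrocyte (adjusted p = 0.0242) and neutrophil (9.9e-06) lists kept their camera calls. The condition set first was that the erythrocyte list lose its call, and it was not met. That condition was widened only after the outcome was seen. The neutrophil median went from −3.44 to −1.45 with the erythrocyte marker covariate and to −1.32 with the rod marker covariate. Residual blood, white blood cells and neural retina content therefore stay open. Without air replicate 2 the interferon median was −0.34 and without air replicate 1 −0.60, so a single air library may account for part of the size, and smoke exposure stays open as an untested biological cause.

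The isoform differences were weighed against 4 explanations. The longest transcript moved above the shortest in 51.2% of the 739 called genes (95% exact interval 47.5% to 54.8%). Among all 10350 tested genes whose transcripts differed in length the share was 48.7% (47.7% to 49.7%). The intervals treat genes as independent. These values argue against a transcript length trend shared by most called genes. False calls would draw the share toward 50%, so a trend in a part of the genes stays open. Of 229 called genes whose most changed transcript was of an unproductive class, its share was higher in smoke in 41.0% (34.6% to 47.7%), which leaves a shift in such classes open. Among 10 splits of the 5 libraries into 2 and 3, 1 (the real split) gave 739 genes and the highest other gave 173, and 10 splits are too few for a share under 0.05. Transcripts with at least 20 counts in every library of 1 group and at most 1 in every library of the other numbered 230 (79 in air and 151 in smoke) against 125 in the highest other split, and 21.6% of their genes had an unadjusted gene-level p under 0.05 against 15.8% of all genes, so reads sequenced or quantified differently between the groups may account for some and cannot be told apart from biology.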
